A study of Mus musculus with 4 samples.

How the data were processed

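RNA was measured in 4 tumours of the iNRAS-475 mouse melanoma line. Per the labels' protocols, cells were injected into the dermis of nude mice given 2 mg/ml doxycycline in their water. Tumours had reached 200 to 500 mm3 after 6 weeks, when the drug was withdrawn for 24, 48 or 72 h or, for the control, kept. Skin was trimmed off, a piece of about 50 mg was frozen, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 10 ug of total RNA for an Affymetrix mouse array. The arrays were grouped by the treatment the labels give, 1 array per group.

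The deposited table holds 1 intensity per probe set and array on a linear scale. The submitters' processing notes name MAS5 and RMA, with no version or role, so which of them made these values, and how the arrays were scaled, is not given in the sources used here. The table had 45037 probe sets, with intensities from 6.99 to 19970 and medians from 33.3 to 34.0. Many values were exactly equal between arrays: 48.0% of probe sets had a tie between at least 2 arrays and 2.64% were equal on all 4. Ties of this kind shrink differences and the measured spread, and their origin is unknown. Control probe sets were not among those read, so the planned comparison of 3' and 5' control probe sets, a check of RNA quality, was not run.

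Gene symbols came from the platform annotation. Of the probe sets, 34945 had a single symbol, 932 had several and 9160 were not listed there, and only the first kind was used for genes. Of a gene's probe sets the one with the highest mean over the 4 arrays was taken; other probe sets of a gene that differed in direction by over 0.2 were looked up. Genes with a mean level at or above the 40th percentile of probe sets, an intensity of about 24.8, were kept, which left 13525.

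From the deposited intensities the log2 of the value plus a pseudocount of 32 was computed. The pseudocount is close to the median intensity, so it shrinks the differences of dim genes. No further normalization was applied. Each off array was compared with the control as a difference of log2 values, with no p-value, and counts used a difference of at least 1. To show what a shared control alone gives, unchanged arrays were simulated 100 times with each gene's noise drawn, with a random sign, from the difference between 2 real arrays at one of the 200 genes nearest in level, divided by the square root of 2. The count of genes that differ in one direction at all 3 times was repeated with each array as the reference. In the pooled test limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend) compared the 3 off arrays with the control, with Benjamini-Hochberg adjustment; it had 2 residual degrees of freedom and an estimated prior of 0.758. Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6 was used elsewhere.

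The 31 gene lists, the tests and most alternatives were fixed before the data were examined. The lists cover ERK output, the cell cycle (G2/M, S phase, G1), p53 targets, the BCL2 family, pigment genes, neural crest genes, receptor tyrosine kinases, FOXO targets, ribosome biogenesis, glycolysis, oxidative phosphorylation, hypoxia, cholesterol synthesis, stress responses, lysosome, interferon, MHC class I and II, matrix, and 10 sets of markers of other cells (endothelial cells, pericytes, macrophages, neutrophils, lymphoid cells, mast cells, keratinocytes, skeletal muscle, adipocytes and erythroid cells). For each list the median difference was placed among the medians of 10000 random lists of the same size, each member replaced by one of the 200 genes nearest in mean level. Genes were named by a fixed rule: Nras and the ERK list; of genes 2-fold different in one direction at all 3 times, up to 10 each way; the 5 highest and 5 lowest at each time and from 24 to 72 h; 4 members of each list with the greatest mean difference; and the 10 smallest p-values of the pooled test. The genes B2m, Gata2, Pmaip1, Aldoc, P4ha2 and Mybpc2, and those of the 5 later lists in the closing part, were named after their values had been seen.

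On simulated data for the pooled test, with normal noise and no ties, limma called 100 of 100 genes changed by a log2 of 1, 100 of 100 changed by 2 and 11 of 13325 unchanged genes. That noise was far more even than that of the arrays, so these shares do not carry over to them. Of 100 random lists, 3 fell outside the 95% range with no shift and 100 with a shift of 0.5. Alternatives were quantile normalization, median centring, no level filter or one at the 60th percentile, the mean over probe sets, probe sets ending in _x_at or _s_at left out, pseudocounts of 8 and of 4 times 32, each off array left out, limma without trend and limma with hours as a linear term. No pseudocount and the removal of tied genes were added after seeing the data.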

Results

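Gene expression was measured in tumours grown in nude mice from iNRAS-475, a mouse melanoma line in which NRAS can be switched on by doxycycline. NRAS is a small GTPase that activates the RAF, MEK and ERK kinases. The mice drank doxycycline while the tumours grew, and the drug was then withdrawn to follow expression after the loss of NRAS. There was 1 array of a tumour kept on doxycycline, the control, and 1 array each of tumours taken 24, 48 and 72 h after withdrawal. No condition was replicated, so no difference between 2 arrays has a replicate error, and animal, tumour piece and condition cannot be separated. The number of arrays, 4, limits the precision of every value. Median intensity was 33.4 on the control array and 33.3, 34.0 and 33.8 at 24, 48 and 72 h. Differences are given on the scale log2(intensity + 32), which understates those of dim genes, and as off minus on unless another reference is named. A gene is called 2-fold higher or lower where this difference is at least 1 in size.

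The mouse Nras probe sets were higher at 24 h than on doxycycline and differed little at 48 and 72 h. The brightest had an intensity of 163 on the control array, 256 at 24 h and 163 at both 48 and 72 h. The others read 86.2, 108, 94.5 and 83.8, and 72.9, 95.3, 75.6 and 68.9, over the same arrays. The labels do not give the sequence of the inducible NRAS, so they do not check whether the labels match the state of the transgene.

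ERK pathway output and feedback genes, which are transcribed when ERK is active, were far lower at 48 and 72 h than on doxycycline. The intensity of Dusp6, a phosphatase of ERK, was 1706 on doxycycline, 1338 at 24 h, 334 at 48 h and 156 at 72 h. Dusp4, a related phosphatase, went from 1303 to 1054, 331 and 86.8, and Ccnd1, which encodes cyclin D1, from 9864 to 10149.7, 3222 and 1305. Ier3, the EGF receptor ligand Hbegf, Phlda1, the urokinase receptor Plaur and the feedback inhibitor Spry4 had differences of -1.46, -1.73, -1.65, -1.69 and -1.63 at 48 h and of -2.92, -2.46, -2.39, -1.90 and -1.77 at 72 h, although another Spry4 probe set was at -0.24. Fos departed from the rest at 48 h, when it alone lay above the control, at 0.26. It was at 0.09 at 24 h and at -0.45 at 72 h, when Spry1, Epha2 and Epha4 differed by less (-0.42, -0.37 and -0.24). Of the 23 genes measured from this list, 15 were below the control at 24 h, 22 at 48 h and 23 at 72 h, and 0, 10 and 14 were 2-fold lower. Some of these calls rest on 1 probe set: at 72 h other probe sets of Spry2, Etv4, Lif and Fosl1 were at -0.08, 0.05, -0.04 and -0.51. Those of Spred2 lay between -0.39 and 0.00 and of Etv5 between -1.70 and -0.53. Other probe sets of Ccnd1 (-3.08 to -2.96) and Hbegf (-2.20) went with the brightest. The list's median difference was -0.16 at 24 h, -0.89 at 48 h and -1.24 at 72 h, below all of the 10000 random lists matched on mean level at each time. Those lists had 95% of their medians between -0.04 and 0.12, -0.12 and 0.10, and -0.11 and 0.13 in turn. From 24 h to 72 h, which leaves the control array out, the list's median was -1.34, with 22 of 23 genes lower. In the pooled limma test of the 3 off arrays against the control 0 of the 23 genes passed, over all genes or adjusted over the list alone, where the lowest adjusted p was 0.116. Without the 72 h array the median of the list's mean difference over the off arrays was -0.41, against -0.68 with it, and without the 24 h array it was -1.09.

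**Figure D1:**
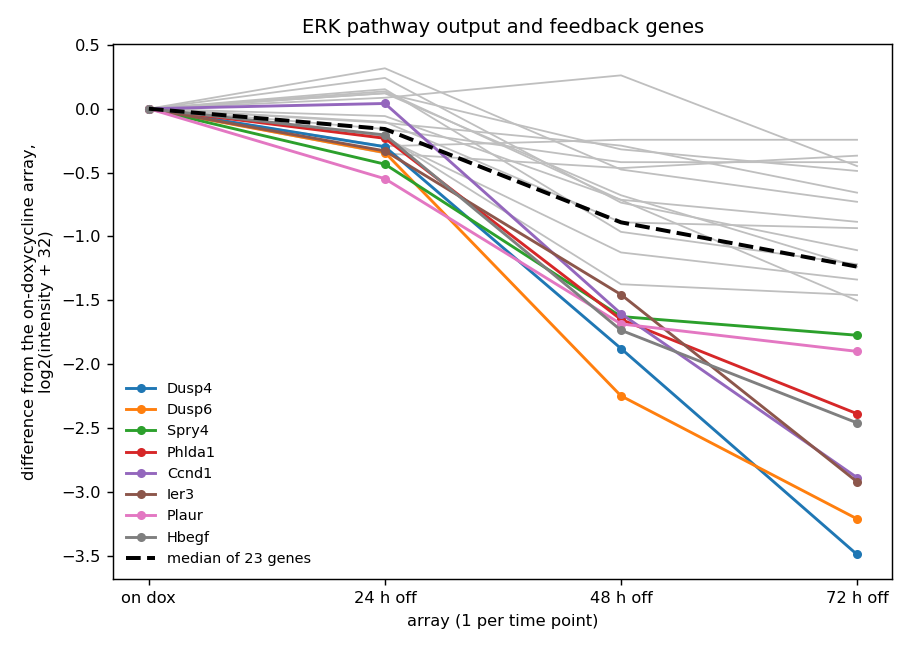
Difference from the on-doxycycline array, on the scale log2(intensity + 32), for the 23 measured ERK pathway output and feedback genes (y axis) on each of the 4 arrays (x axis, 1 array per time). Coloured lines are the 8 genes with the greatest mean difference, grey lines the others, and the dashed line is the list's median, which lies at -0.16, -0.89 and -1.24.

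At 24 h off doxycycline the genes furthest above the control were MHC class II genes, Iigp1, an interferon-inducible GTPase, and Acta1, a muscle actin. The class II genes H2-Aa, H2-Ab1 and Cd74, the invariant chain, had intensities of 245, 414 and 378 on doxycycline and 2179.6, 2272 and 2510.4 at 24 h. Iigp1 was higher by 2.71, with another probe set at 1.12, and Acta1 by 1.99. S phase genes were also higher: 20 of 22 lay above the control, with a median of 0.56, and Rrm2, a subunit of ribonucleotide reductase, and Mcm6, a subunit of the replicative helicase, were higher by 1.52 and 1.14. The lowest differences were those of Hp (haptoglobin), at -1.99, Ucn2 (urocortin 2), at -1.39, Sfrp2, at -1.31, the fatty acid binding protein Fabp4, at -1.19, and Nefm, a neurofilament subunit, at -1.11. In all, 36 of 13525 genes were 2-fold higher and 9 were 2-fold lower, and 95% of all differences lay between -0.37 and 0.47. With a pseudocount 4 times as large the counts were 12 and 1.

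At 48 h off doxycycline several genes that were bright in the control tumour were much dimmer. Slc14a1, a urea transporter, went from an intensity of 2291 to 227, Hmga2, a chromatin protein, from 3591 to 380.2, and Igfbp3, which binds insulin-like growth factors, from 6199 to 884. Tinagl1 and the uridine phosphorylase Upp1 had differences of -2.75 and -2.69. The highest differences were those of Aspn (asporin), 2.75, Matn2 (matrilin 2), 2.56, the potassium channel Kcna1, 2.51, the syntrophin Sntb1, 2.26, and the cadherin Cdh19, 1.95. Other Sntb1 probe sets lay between 0.12 and 1.01. In all, 100 genes were 2-fold higher and 140 were 2-fold lower, and 95% of all differences lay between -0.68 and 0.64. When a gene's probe sets were averaged instead of taking the brightest, the counts were 54 and 81.

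At 72 h off doxycycline these 3 genes were lower still, and most skeletal muscle, fat and matrix genes were higher than on any other array. Slc14a1, Hmga2 and Igfbp3 had differences of -4.64, -4.50 and -4.50, the cGMP-dependent kinase Prkg2 of -4.23 and Dusp4 of -3.49. Other Hmga2 probe sets lay between -4.23 and -0.65. The highest were the muscle genes Acta1 (4.12), Tnnc2 (3.83, fast troponin C) and Myh4 (3.53, a fast myosin heavy chain), with Kcna1 (4.01) and Matn2 (3.68). Myh4 read 11.5, 9.88 and 11.5 on the control, 24 h and 48 h arrays and 470 at 72 h. In all, 305 genes were 2-fold higher and 217 were 2-fold lower, and 95% of all differences lay between -0.80 and 0.95. When probe sets were averaged the counts were 193 and 139.

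The 3 times overlapped most between 48 and 72 h. Of the 2-fold higher genes 71 were shared between these times, and of the 2-fold lower genes 116, where independent lists would share 2.26 and 2.25. Between 24 and 48 h 11 higher and 3 lower genes were shared (0.27 and 0.09 for independent lists), and between 24 and 72 h 19 and 3 (0.81 and 0.14). A shared control makes unchanged arrays overlap too. In 100 simulations of unchanged arrays against 1 control, with noise drawn from the differences between the control and 24 h arrays, a median of 5 higher and 5 lower genes were shared, and at most 15 and 12. With noise drawn from the differences between the 48 and 72 h arrays the medians were 28 and 27 and the highest counts 47 and 40. The counts shared between 48 and 72 h lay above these, whereas those shared with 24 h lay below these medians. Against the smaller noise, the 11 and 3 shared between 24 and 48 h lay within the highest counts. So did the 3 lower genes shared between 24 and 72 h, but the 19 higher genes exceeded the highest count, 15. Noise drawn from the differences between the control and 72 h arrays holds any effect of withdrawal as well. It gave medians of 98 and 95 and highest counts of 125 and 118, which the 71 and 116 shared between 48 and 72 h did not exceed. This test was chosen after the overlaps had been seen, and the noise of these arrays is unknown. The 1 control array cannot be split, so part of the overlap, of unknown size, may come from it.

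Genes 2-fold higher at all 3 times were Irgm1, an interferon-inducible GTPase, Cybb, the phagocyte NADPH oxidase subunit, the long noncoding RNA Malat1, the linker histone H1f2, the class I and II genes H2-K1, H2-Aa and Cd74, and Aspn. Irgm1 was higher by 1.84, 1.35 and 1.58 at 24, 48 and 72 h, Cybb by 1.58, 1.34 and 1.97, and Malat1 by 1.34, 1.44 and 1.33, with its other probe sets between 0.04 and 1.25 at 72 h. Genes 2-fold lower at all 3 times were Ucn2 (-1.39, -1.90 and -2.02), Nefm (-1.11, -2.54 and -2.71) and Sdc4, a syndecan (-1.03, -1.41 and -2.11). Another Sdc4 probe set was at 0.21, -0.06 and -0.26, and other H1f2 and H2-K1 probe sets lay between -0.17 and 1.17 and between 0.07 and 1.01 at 72 h. At 24 h other Cybb probe sets lay between 0.57 and 0.88, and another Aspn probe set was at 0.52. The counts at all 3 times, 8 and 3, were 71 and 116 without the 24 h array and 19 and 3 without the 48 h array. With a pseudocount 4 times as large they were 2 and 0, with none 18 and 3, and with the mean over probe sets 3 and 2. With the 24, 48 or 72 h array as the reference in place of the control, 3, 2 and 22 genes were 2-fold higher on all of the other arrays and 7, 1 and 100 were 2-fold lower. So the array that stood furthest from the other 3 by this count was the 72 h array, not the control. Of all genes, 51.2% had 3 differences of one sign, where exchangeable arrays sharing a reference give 50%.

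From 24 h to 72 h off doxycycline, a comparison that does not use the control array, the genes with the greatest differences included several of those named above. Hmga2, Slc14a1, Igfbp3, Prkg2 and the R-spondin receptor Lgr6 were lower at 72 h than at 24 h, with differences of -4.58, -4.51, -4.48, -4.25 and -3.93. Kcna1 was higher by 4.16, the proteoglycan Lum (lumican) by 4.08, Matn2 by 3.71, Fabp4 by 3.62 and the proteoglycan Dcn (decorin) by 3.61, although another Dcn probe set was only 0.17 above the control at 72 h. At 48 h these genes lay between the other times or close to one of them: Lum read 162, 939 and 3252 at 24, 48 and 72 h, and Hmga2 3799.5, 380.2 and 127.8. In all, 262 genes were 2-fold higher at 72 h and 247 were 2-fold lower. With a pseudocount 4 times as large the counts were 147 and 118.

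No gene passed the pooled test of the 3 off arrays against the control. limma called 0 of 13525 genes at an adjusted p under 0.05, the lowest adjusted p was 0.111, and 1889 genes had an unadjusted p under 0.05 (890 higher and 999 lower), where chance gives 676. The class I genes H2-K1, H2-D1 and B2m, which were higher by a mean of 1.15, 0.89 and 0.69, passed when adjusted over the list alone (limma adjusted p = 0.0200 for each). So did the mast cell genes Cpa3, Cma1, Mcpt4 and Gata2, the p53 targets Cdkn1a and Pmaip1, the pigment genes Mc1r and Dct, Aldoc of glycolysis and P4ha2 of hypoxia. Over 8 of the 31 lists there were 15 such calls, 9 of them of genes with equal values on at least 2 off arrays. Equal values lower the measured spread: 10 of the 10 genes with the smallest p, among them Casp1 (47.1 on the control and 84.4 on each off array) and Tmem123, had such ties, against 27.3% of all genes. With genes tied between any arrays left out, a test chosen after the ties had been seen, 8538 genes remained, limma called 0 of them, the lowest adjusted p was 0.832 and 436 had an unadjusted p under 0.05, where chance gives 427. Adjustment over a list alone took no account of there being 31 lists. The pooled test treats 3 different times as one group and assumes that the single control varies as they do. With the 72 h array as the reference limma called 2 genes, the muscle genes Myh4 and Mybpc2 (adjusted p = 0.0276 for each).

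The medians of ribosome biogenesis, glycolysis and sterol synthesis genes were below the control at 48 and 72 h, while those of S phase and G2/M genes were near 0. Of the 15 glycolysis genes measured, 12 were below the control and 3 above it at each of these times. Ribosome biogenesis and MYC target genes had medians of 0.04, -0.41 and -0.50 at 24, 48 and 72 h, with all 19 below the control at 48 and 72 h, among them Fbl, a nucleolar methyltransferase, at -0.85 and -1.35. Medians were -0.21, -0.34 and -0.55 for glycolysis, -0.06, -0.33 and -0.35 for cholesterol and fatty acid synthesis, and 0.02, -0.50 and -0.20 for the unfolded protein and integrated stress response, the last of these within the range of 95% of random lists. The hexokinase Hk1, the glucose transporter Slc2a1, the sterol enzymes Fdps and Sqle and the asparagine synthetase Asns had differences at 72 h of -1.48, -1.17, -1.66, -1.61 and -2.45. Atf3, in the stress list, went the other way, at 2.27. Oxidative phosphorylation genes (0.06, -0.14 and -0.20) stayed within the range of 95% of random lists, and hypoxia genes (-0.10, -0.01 and -0.18) lay below it at 24 and 72 h. S phase genes, at 0.56 at 24 h, were at 0.00 and -0.07 later, and G2/M genes at 0.20, 0.00 and 0.00. The list of G1 cyclins, CDKs and CDK inhibitors had medians of -0.03, -0.21 and -0.17, the last pair below the range of 95% of random lists, with the inhibitors Cdkn2b at -1.73 and Cdkn1a at -0.73 at 72 h as well as Ccnd1.

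The medians of FOXO target and lysosome genes were above the control at 72 h, and single apoptosis and pigment genes differed at that time while the medians of their lists lay near 0. FOXO targets had medians of 0.12, 0.30 and 0.45: Txnip, an inhibitor of glucose uptake, was higher by 2.09 at 72 h, and the PI3K inhibitor Pik3ip1 by 1.31. Lysosome genes had medians of -0.01, 0.13 and 0.41, with Lamp2 and Psap at 1.20 and 0.93; macrophage genes, whose median was 0.92, were higher on the same array. The BCL2 family's median was near 0 (-0.03, -0.02 and 0.05), but Bcl2l11, which encodes the death-promoting BIM, was higher by 0.53, 1.24 and 1.46, and Bcl2l1, which encodes the survival protein BCL-XL, differed by 0.27, -0.996 and -0.92, although another Bcl2l1 probe set was at -0.31 at 24 h. p53 targets had medians of -0.10, 0.05 and 0.04, the first below the range of 95% of random lists, with Trp53inp1 at 2.01 and Phlda3 at -1.37 at 72 h, although another Trp53inp1 probe set was at 0.03. Pigment genes had a median of -0.14 at 24 h, below the range of 95% of random lists, with 11 of 14 genes below the control, and of -0.01 and 0.00 later. Neural crest and dedifferentiation genes (-0.01, 0.00 and 0.08) and receptor tyrosine kinases (0.02, 0.05 and 0.00) stayed within that range. Mitf, the melanocyte transcription factor, and Pmel, a melanosome protein, were higher by 0.84 and 1.14 at 72 h, and the progenitor gene Nes (nestin) was lower, at -2.09, although its other probe sets were at -0.50 and -0.32.

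**Figure D2:**
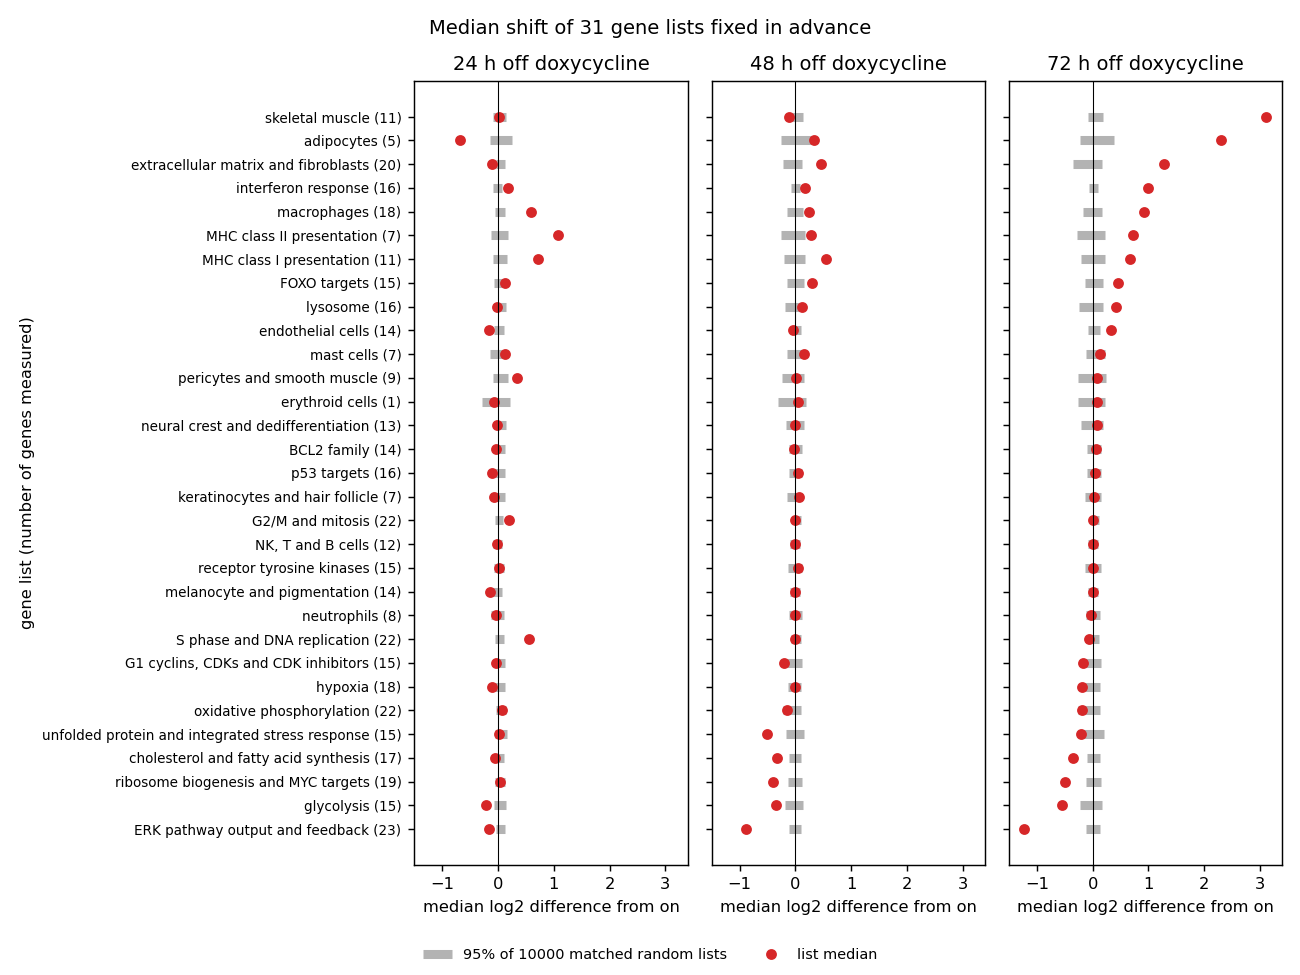
Median log2(intensity + 32) difference from the on-doxycycline array (x axis) of each of the 31 gene lists (y axis, with the number of genes measured) at 24, 48 and 72 h. Points are list medians and grey bars hold 95% of the medians of 10000 matched random lists; ERK output genes lie lowest at 48 and 72 h (-0.89 and -1.24) and skeletal muscle genes highest at 72 h (3.10).

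The medians of MHC, interferon response and macrophage genes were above the control at all 3 times, in more than one time course. MHC class I genes had medians of 0.71, 0.55 and 0.66, with all 11 above the control at each time. MHC class II genes had 1.07, 0.28 and 0.72, interferon response genes 0.18, 0.17 and 0.99, and macrophage genes 0.59, 0.24 and 0.92. Class II genes were highest at 24 h, whereas Ifit3, Ifit1 and Oasl2, induced by interferon, were higher by 2.66, 2.35 and 1.91 at 72 h but by 0.32, 0.06 and 0.51 at 24 h. The macrophage genes Lyz2, Mpeg1 and Cd68 were higher at 72 h by 1.82, 1.78 and 1.49; Lyz1 and Lyz2 are close copies, as are H2-K1 and H2-D1, and their values are uncertain where probe sets share signal. Neutrophil genes (-0.04, -0.01 and -0.02), NK, T and B cell genes (-0.02, 0.00 and 0.00) and mast cell genes (0.13, 0.16 and 0.13) stayed within 95% of random lists. Many markers of these cells were dim or not measured.

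The median of matrix genes was above the control at 48 and 72 h, and those of muscle and fat genes were far above it at 72 h. Extracellular matrix and fibroblast genes had medians of -0.10, 0.46 and 1.28, and 18 of 20 were higher at 72 h than at 48 h. Col1a1, a collagen chain, read 3797, 4046, 9348 and 18004.8 on the control, 24, 48 and 72 h arrays, and Postn (periostin) 781, 754, 1871 and 5879, while Timp1, a protease inhibitor, was lower, at -2.99 at 72 h. Skeletal muscle genes had medians of 0.02, -0.11 and 3.10, and 9 of 11 were 2-fold higher at 72 h. At 24 h the list's mean was 0.32, with Acta1, Tnnc2, Mylpf and Atp2a1 at 1.99, 0.72, 0.44 and 0.32. The 5 adipocyte genes measured had medians of -0.67, 0.34 and 2.30, with 3 above and 2 below the control at 48 h, and Adipoq (adiponectin) read 64.0, 15.6, 58.9 and 352. Endothelial genes had medians of -0.16, -0.04 and 0.33, pericyte and smooth muscle genes 0.34, 0.01 and 0.08, keratinocyte and hair follicle genes -0.07, 0.06 and 0.02, and the 1 erythroid gene measured, Alas2, was at -0.06, 0.04 and 0.08. The muscle and fat signal, greatest on the 72 h array, stands beside every comparison that uses that array. Of the 93 list medians, 45 lay outside the middle 95% of their random lists, where chance gives 4.65 for lists of unrelated genes; genes of a list vary together, so these percentiles describe the 4 arrays and not the conditions.

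**Figure D3:**
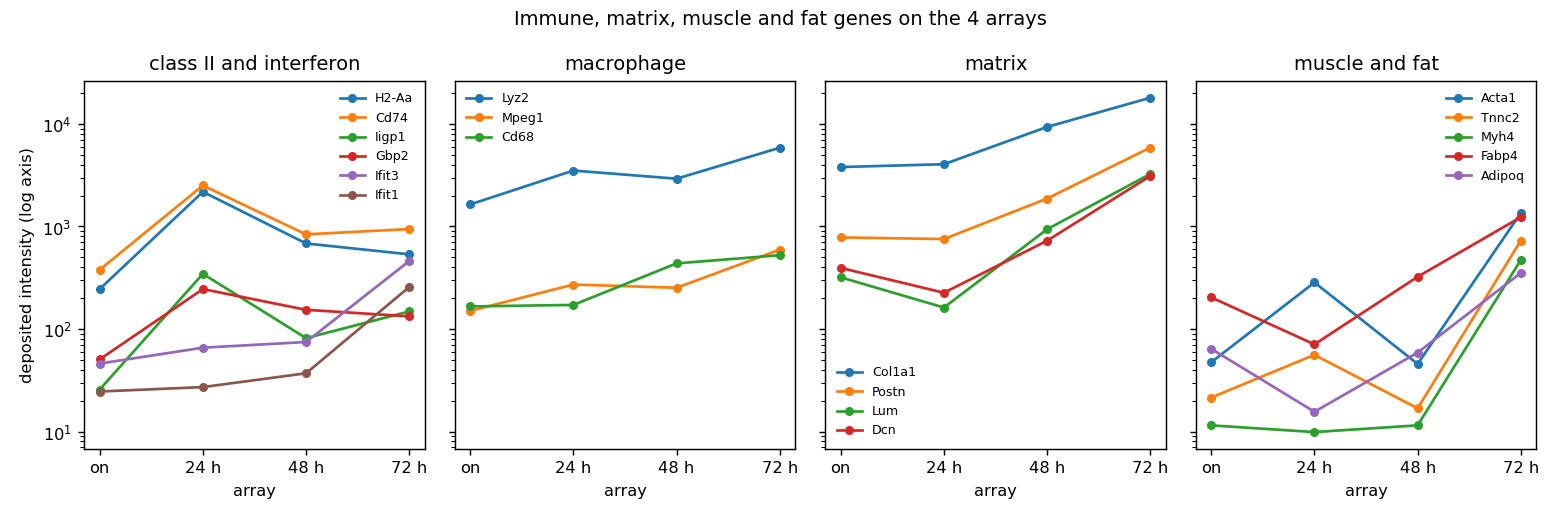
Deposited intensity (y axis, log scale) of class II and interferon, macrophage, matrix, and muscle and fat genes on the 4 arrays (x axis, 1 array per condition). H2-Aa peaks at 24 h (2179.6), Ifit3 at 72 h (460), Col1a1 is higher at 48 and at 72 h, and Myh4 stands out at 72 h (470).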

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

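The tests of muscle and connective tissue here were chosen after the list medians had been seen, and so was the criterion for singling out a list: medians of opposite sign at different times, each outside the middle 95% of its matched random lists. With 1 array per time, none of these differences between times was tested against replicate error. Matrix and fibroblast genes lay at -0.10 at 24 h, 0.46 at 48 h and 1.28 at 72 h. Endothelial genes lay at -0.16 at 24 h and 0.33 at 72 h. Skeletal muscle genes lay at -0.11 at 48 h and 3.10 at 72 h, and adipocyte genes at -0.67, 0.34 and 2.30. Among the 4306 probe sets past the level filter that have several symbols or none in the annotation, which entered no gene comparison, 11, 24 and 55 were 2-fold higher than the control at 24, 48 and 72 h and 4, 17 and 25 were 2-fold lower.

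The medians of muscle, fat and matrix genes were all higher on the 72 h array, and at 48 h matrix genes lay at 0.46 with 15 of 20 above the control and fat genes at 0.34 with 3 of 5. Muscle of the host animal in the 72 h tumour piece is a candidate source of the muscle signal: 9 of 11 measured muscle genes were 2-fold higher there, with intensities of 1353 for Acta1, 916 for Atp2a1 and 729 for Tnnc2, and only 1 of the 11 was over 100 on the control array, though Acta1 and Tnnc2 were also higher at 24 h, by 1.99 and 0.72. Muscle tissue was argued against as the source of the matrix signal at 48 h, where the muscle list's median was -0.11 and its upper quartile -0.04 while the matrix median was 0.46. Fat or connective tissue of the host cannot be told apart from a difference in the tumour's own matrix at 48 h, where the adipocyte median was 0.34 with a lower quartile of -0.07, or at 72 h, where it was 2.30 on the single array on which matrix genes were highest. Time off doxycycline stays open for the matrix genes as a biological explanation, untested, since each time is also 1 tumour piece.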

How the results depend on the processing

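No pseudocount and the removal of tied genes were chosen after seeing the data, as were the tolerances used to call a value moved (1.5 times for a count, 1 SD of the random lists' medians for a list, 1 standard error for a gene). Quantile normalization, median centring, the level filters and the removal of _x_at and _s_at probe sets left every count of genes within 1.5 times. Over all alternatives 99 counts stayed within that bound and 27 did not. A pseudocount 4 times as large gave 12 higher and 1 lower at 24 h, 38 and 58 at 48 h, 167 and 115 at 72 h, 147 and 118 from 24 to 72 h, and 2 and 0 at all 3 times. No pseudocount gave 67 and 26 at 24 h, 180 higher at 48 h, 496 higher at 72 h and 18 higher at all 3 times. A pseudocount of 8 gave 18 lower at 24 h and 13 higher at all 3 times. Both directions of these moves follow from how a pseudocount shrinks dim genes. The mean over probe sets gave 5 lower at 24 h, 54 and 81 at 48 h, 193 and 139 at 72 h, 154 lower from 24 to 72 h and 3 higher at all 3 times; the cause was not tested. Genes different at all times numbered 71 higher and 116 lower without the 24 h array and 19 higher without the 48 h array, since fewer arrays had to agree. The pooled limma test called 0 genes in all 16 fits with the control as reference, with lowest adjusted p between 0.0601 and 0.832.

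The ERK list's median stayed below 0 in every alternative. At 24 h it was -0.22 with quantile normalization, -0.090 with the mean over probe sets, -0.21 without _x_at and _s_at probe sets and -0.11 with the larger pseudocount. At 48 h it was -0.83, -0.65, -0.96 and -0.65 in that order, -0.96 with the filter at the 60th percentile and -0.98 with no pseudocount. At 72 h it was -0.84 with the mean over probe sets, -1.34 both without _x_at and _s_at probe sets and with the stricter filter, -0.82 with the larger pseudocount, -1.68 with a pseudocount of 8 and -1.75 with none. The median of mean differences over the off arrays was -0.51, -0.50, -0.77 and -0.80 with the mean over probe sets, the larger pseudocount, a pseudocount of 8 and none, and -1.09, -0.56 and -0.41 without the 24, 48 and 72 h array.

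Of medians of mean differences, that of S phase genes turned to -0.048 without the 24 h array, and those of skeletal muscle and adipocyte genes to -0.027 and -0.17 without the 72 h array, as did Myh4, to -0.027: each rests on 1 array. The list of G1 cyclins, CDKs and CDK inhibitors turned to 0.025 without _x_at and _s_at probe sets; the cause was not tested. Each list was counted separately at each time and for the mean over the off arrays, or for that mean alone where an off array was left out. Each named gene was counted once per alternative, by its mean difference. Of these, 911 list values stayed within their tolerance and 290 moved without turning, and 1871 gene values stayed and 129 moved. The share of 2-fold genes that were higher at 24 h was 80.0%, 71.1% with quantile normalization and 72.0% with no pseudocount. Many genes lie near the median intensity of about 33, where a pseudocount of like size shrinks any difference.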

Other observations

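The tests of tumour cell content and both tests of macrophages were chosen after the results they address had been seen. Those of dendritic cells, Schwann and glial genes, interferon gamma genes and type I interferon genes were written before their members' values were looked at, though after the patterns had been seen, and all 5 gene lists used here were made at that stage.

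The median of type I interferon genes outside the lists of the report was highest at 72 h. The 14 measured had medians of 0.13, 0.14 and 0.61 at 24, 48 and 72 h, and Trim30a, Ifi27 and Parp14 were higher by 1.16, 1.15 and 0.97 at 72 h. It was asked whether such a set peaks at 72 h and an interferon gamma set at 24 h. From 24 to 72 h the type I set's median was 0.47, above all of the 10000 matched random lists, with 12 of 14 genes higher, which is consistent with the first hypothesis. Macrophage genes were also higher from 24 to 72 h, by a median of 0.47 with 14 of 18 higher, so a difference in cell content was not separated from a difference in interferon response. The 7 interferon gamma genes measured, among them Igtp (1.04 at 24 h and 0.58 at 72 h), Irf1 (0.75 and 0.73) and Gbp7 (1.28 and 1.28), had medians of 0.75 at 24 h and 0.58 at 72 h. Gbp7 and Icam1 were exactly equal at 24 and 72 h, ties of unknown origin that draw the set's difference between these times toward 0. Of the rest, 1 was higher at 72 h and 4 were lower. Their median difference from 24 to 72 h was -0.018, at percentile 20.7 of random lists, with a lower quartile of -0.55. By the rule written before, a median at or above the 2.5th percentile of random lists, -0.16, counted against the second hypothesis, so its prediction was not met. Only 3 of these genes were over 100 on the control array, so the test is weak.

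Cdh19, a cadherin of the Schwann cell lineage, Kcna1 and Matn2 were among the highest genes at 48 h, and it was asked whether a wider Schwann and glial set was higher too. The 12 genes measured had a median of 0.038 at 72 h, at percentile 76.3 of random lists, which does not bear the hypothesis out. It does not exclude it either, since members went both ways, 7 above and 4 below the control, with an upper quartile of 0.90. Scn7a was highest, at 2.003, Cnp was at 1.10, Ngfr and L1cam were at 0.90, and Egr2, also an immediate early gene, was lowest, at -1.44. Ngfr also belongs to the neural crest list of the report, so its value had entered a median already seen.

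ERK output genes were lower at 48 and 72 h, and a smaller share of tumour cells in the piece is a possible explanation that would lower all genes of the tumour cells alike. As a set, 8 neural crest lineage genes were not lower by as much as the ERK list, which was at -1.24 at 72 h and -0.89 at 48 h. Their median was -0.0086 at 72 h, with a lower quartile of -0.19, and 0.26 at 48 h, with a lower quartile of -0.04. These values cannot decide the question, since most of the 8 were chosen with their values already seen. Of the 8, Sox10, Erbb3, S100b, Foxd3 and Cdh19 had been looked at when the list was made. Tfap2b belongs to a list of the report. The other 2, Tfap2a and Mia, were at -0.28 and -0.15 at 48 h and at -0.45 and -0.15 at 72 h. Both were lower, as a smaller share of tumour cells predicts, though Tfap2a by less than the ERK median. Mia and Tfap2b read only 43.2 and 55.0 on the control array. Even at the lowest intensity of the 72 h array, 6.99, they could not reach the ERK median of that time on this scale. Sox10 read 3771 on the control array and differed by 0.03 at 72 h, though host nerve expresses it as well. Lower ERK signalling after withdrawal stays open as a hypothesis, beside a smaller share of tumour cells and differences between animals, which 1 array per time could not test.

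Class II genes were highest at 24 h, and more macrophages at that time is a possible explanation. Macrophage genes were also higher at 24 h, by a median of 0.59 with 17 of 18 above the control, and were at 0.24 at 48 h, as class II genes went from 1.07 to 0.28, so macrophages cannot be told apart from other sources of the class II difference from the control, which was the larger. They were argued against for the difference between 24 and 72 h, when macrophage genes were higher at 72 h by a median of 0.47, with a lower quartile of 0.05, while 7 of 7 class II genes were lower. More dendritic cells could not be excluded or borne out: their 5 measured genes had a median of 0.046 at 24 h, but only 1 was over 100 on the control array. A response of the tumour or its host to withdrawal, including a different state of its macrophages, and a difference between animals stay open and untested.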
